A study of Caenorhabditis elegans with 6 samples.

How the data were processed

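RNA from 3 wild type (WTN2) and 3 flcn-1 mutant (RB1035) samples was measured on Agilent 1-colour arrays. Per the labels' protocols, animals were synchronised by egg preparation, grown on agar with OP50 bacteria and picked as young adults before reproduction. RNA was extracted with a miRNeasy kit after bead homogenisation and labelled with Cy3 by the Low Input Quick Amp kit. Samples were grouped by the strain in their titles, and the labels' design text calls the replicates biological triplicates.

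Per the file headers, spot intensity values were extracted with Agilent Feature Extraction 10.7.3.1 from a slide with 4 arrays whose probes were designed against build ce4 (WS170). Per the file headers, the processed signal intensity is the spot signal after subtraction of a spatial background surface and division by a fitted multiplicative surface, with no normalization between arrays. The deposited files also hold median spot and background intensity values and flags for well above background, outlier and saturated spots. On mutant 2 no multiplicative surface was divided out, per the file headers. On mutant 3 that surface varied most (root mean square of 0.30), and the spike-in slope was lowest, at 0.896. The median coefficient of variation between copies of the same probe was 22.4% and 20.9% on mutants 2 and 3, against 8.19% to 10.9% on the other arrays. The deposited series table holds log2 values whose medians were 7.61 or 7.62 on each array. How the authors made it is not given in the sources used here. Its order of probes on an array followed the median spot signal (Spearman's rho across probes of 0.994 to 0.998), and its nearly equal distributions look like those left by quantile normalization. Any centring of single genes was not seen, and its values are levels, not ratios.

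Each array holds 45220 spots, of which 1417 are controls and were left out. The remaining 43803 spots are 43603 probes, and spots of the same probe were averaged. The log2 of the processed signal minus each array's 75th percentile over these probes was analysed. Probes with an outlier flag on any array (133) were left out, and no spot was saturated. Probes were kept when well above background on at least 3 of 6 arrays, which left 31236. A gene was represented by its brightest probe over all 6 arrays, and 4510 tested genes had several probes. Where probes of a named gene that changed disagree in size, the report gives their range.

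The files name probes by sequence names or accessions of the array's design. These were matched to a gene table of assembly WBcel235: 30975 probes by sequence name and 3342 by accession. For 1477 accessions no match was found, 1077 sequence names absent from the table kept the file's name, and 6732 probes have other identifiers. In all 35394 probes were named, for 20436 genes, and 8209 were not. Because the array design and the table use different builds, no coordinates are given. The table served for names, chromosomes and the order of neighbouring genes.

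Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 19822 features, of which 15543 are named genes and 4279 are unnamed probes. The threshold was an adjusted p of 0.05. Where a group was not well above background on any array, the fold is a lower limit. Gene lists (34, with at least 5 tested members each) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Whole animals hold every tissue, so lists of tissue and stage markers were included. The replicate numbers in the labels were not used in the main model. Slide and scan fall together and each slide holds both strains, so values are also given within slides and with slide as a block.

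Genes were named by a rule fixed before the data were examined. It takes up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold whose arrays do not overlap between strains and whose probe is well above background on all arrays of a strain. It adds flcn-1 and 15 further genes of interest, and up to 4 members with the smallest adjusted p in each list described. Neighbours of the changed genes on chromosome V were named after their values were seen. Probes without a gene name are counted only.

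The procedure was tested on simulated data of this comparison with 19822 features, 200 of them changed. It recovered 0% of 2-fold, 76.3% of 4-fold and 98.7% of 8-fold changes on average, so most 2-fold changes are out of reach with 3 arrays per strain. Lists shifted by 0.5 on the log2 scale were called in 10 of 10 cases with both correlations, and 0 of 160 others were called with the preset one; simulated genes varied independently of each other. Alternatives were normexp background correction (offset 50), quantile normalization, median centring, no filter and a filter on all 6 arrays, the mean of a gene's probes, every probe on its own, a variance trend with robust estimation, array weights, the series table, replicate and slide blocks, and leaving out each array. The normexp offset is added to every signal and so shrinks differences that reach down to dim signals. A smaller normexp value of a dim gene is therefore in part set by the method. The planned normexp used mean spot signals, but the files hold median signals, which were used in their place. The change to median signals and the fit on slide 2 alone were chosen after the data were seen.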

Results

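Transcript levels were measured in whole young adult Caenorhabditis elegans that had not yet begun to reproduce. The wild type, titled WTN2 in the labels, was compared with strain RB1035, which carries a mutant allele of flcn-1. Per the series' design text RB1035 had been backcrossed 8 times. The gene flcn-1 is the worm counterpart of folliculin, a tumour suppressor in humans that works with AMP-activated protein kinase and the TOR pathway. Each strain was represented by 3 arrays, described as biological triplicates, each hybridised with 1 RNA sample labelled with Cy3. Between 68.0% and 73.0% of the 43603 probes were well above background on an array. The number of arrays, 3 per strain, limits the precision of every value. The arrays lay on 2 slides. Slide 1 held wild type 1 and mutant 1, and slide 2 held the other 4 arrays. All differences are log2 signals of the mutant minus those of the wild type, after each array's 75th percentile was subtracted.

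The first comparison concerned flcn-1 itself. Its transcript was detected well above background on all 6 arrays by 4 probes. By the brightest probe the level of flcn-1 was 0.37 ± 0.32 in the wild type and 0.26 ± 0.32 in the mutant (SD, n = 3 each). The difference was -0.11 by limma, with a 95% confidence interval from -0.8 to 0.58 (adjusted p = 0.904). The remaining probes differed by -0.11, -0.07 and 0.22. The sources used here do not give the place of the allele's lesion relative to these probes, so the level of flcn-1 does not check the strain labels. The sign of this difference turned to 0.07 without wild type 1 and without mutant 1.

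The second comparison asked which transcripts differ between flcn-1 mutant and wild type adults. Of 19822 features tested with limma, 20 changed, each by at least 2-fold: 16 fell and 4 rose. They comprise 10 named genes and 10 probes without a gene name. Among named genes the largest falls took 3 genes of chromosome V from well above background on all 3 wild type arrays to not well above background on any mutant array by their brightest probes. F56A4.3 fell at least 654-fold (adjusted p = 6.99e-06), the pseudogene Y102A5C.6 at least 442-fold (adjusted p = 1.14e-05) and srbc-15, a pseudogene of the chemoreceptor family, at least 195-fold (adjusted p = 2.62e-05). These lower limits set the mean of the bright group against the dimmest level still well above background, or the probe's own level where that was higher. They hold for the processed signal only: with normexp on median signals F56A4.3 differed by -6.55, Y102A5C.6 by -5.64 and srbc-15 by -5.01, all still past the threshold. Of the 6 probes of F56A4.3, 2 stayed well above background on all mutant arrays, and its probes differed by -11.36 to -3.16. Whether those 2 probes report F56A4.3 alone was not tested.

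Other losses were smaller. Y102A5C.36 fell at least 27.9-fold (adjusted p = 2.6e-05), the pseudogene Y102A5C.35 at least 17.1-fold by its brightest probe (adjusted p = 0.00111), C07G1.7 of chromosome IV at least 4.82-fold (adjusted p = 0.00079), and fbxa-110, a pseudogene of the F-box family, at least 2.25-fold (adjusted p = 0.0287). The 3 probes of Y102A5C.35 differed by -5.09 to -3.35, and the 2 of srbc-15 by -9.64 to -9.17. The ABC transporter gene haf-6 of chromosome I was well above background on all 6 arrays and fell by 2.29 ± 0.30 (SE), from 0.72 ± 0.29 to -1.57 ± 0.31 (SD, n = 3 each; limma adjusted p = 0.0441).

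Among named genes, 2 rose, both on chromosome V. Transcripts of phat-5, which encodes a protein of the pharyngeal glands, were not well above background on any wild type array and were so on all 3 mutant arrays, a rise of at least 28.2-fold (limma adjusted p = 3.31e-05). All 5 phat-5 probes were higher, by 4.28 to 6.3, and with normexp the difference of phat-5 was 2.73, still past the threshold. The lysozyme gene lys-7 rose 5.17-fold, by 2.37 ± 0.29 (SE), from 1.03 ± 0.32 to 3.40 ± 0.24 (SD, n = 3 each; limma adjusted p = 0.0309). Among the unnamed probes 8 fell and 2 rose. Of those that fell, 5 report a single transcript contig that could not be tied to a gene, with differences from -10.96 to -9.31.

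**Figure D1:**
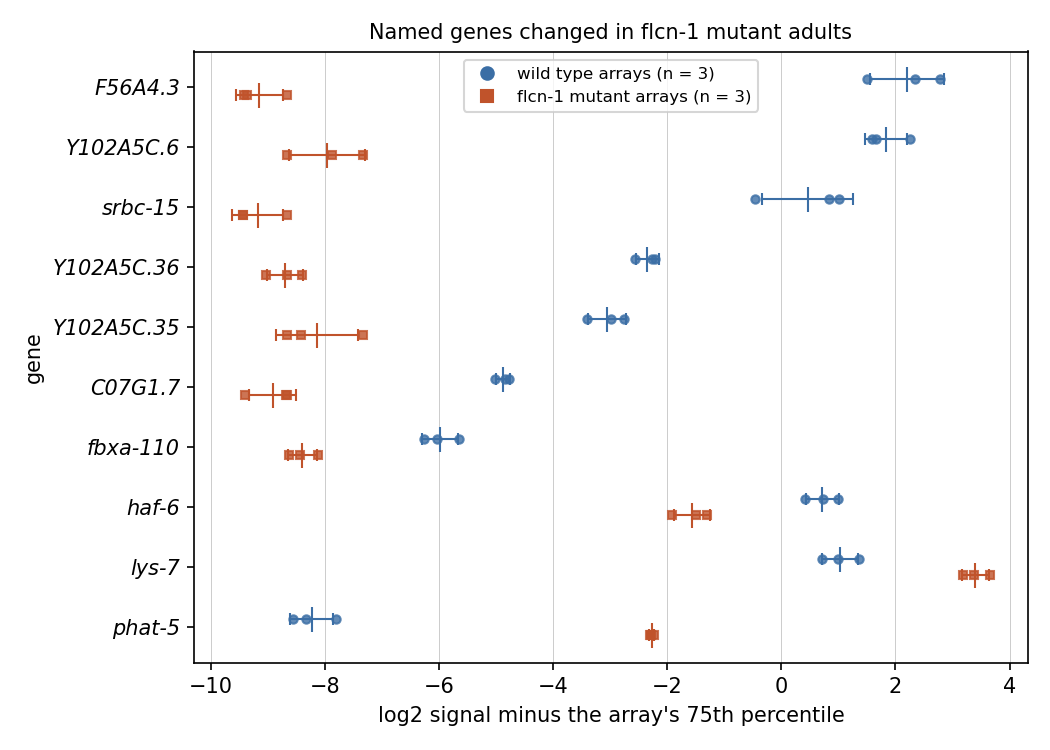
Levels of the 10 named genes that changed, as log2 signal minus the array's 75th percentile. Points are arrays, ticks are means and bars are SDs (n = 3 per strain). F56A4.3 lies at 1.5 to 2.78 on the wild type arrays and at -9.41 to -8.67 on the mutant arrays, and phat-5 at -8.55 to -7.81 and at -2.31 to -2.23.

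Within slide 1, with 1 array per strain, and within slide 2, with 2, each of the 10 named genes differed in the direction given. The naming rule ensures this, as it takes only genes whose arrays do not overlap between strains. Only the sizes within slides are informative. F56A4.3 differed by -12.19 and -10.94, phat-5 by 6.27 and 5.80, lys-7 by 2.93 and 2.09, and haf-6 by -2.64 and -2.11. With slide as a block 18 features changed, without fbxa-110 (adjusted p = 0.0696), haf-6 (0.0743) and lys-7 (0.07). The calls of these 3 genes also ended when any 1 of the 6 arrays was left out, with adjusted p up to 0.203 for fbxa-110, 0.294 for haf-6 and 0.213 for lys-7. Their differences then stayed near those given, at -2.55 to -2.24, -2.44 to -2.12 and 2.22 to 2.54. With normexp background correction, 11 features changed, 10 of them among the 20. C07G1.7, Y102A5C.35 and Y102A5C.36 no longer passed (differences of -0.39, -1.44 and -1.84, adjusted p = 0.863 for each), nor did haf-6 (-2.21, adjusted p = 0.0762) and fbxa-110, whose direction turned (0.08, adjusted p = 0.962). The normexp offset of 50 shrinks differences that reach down to dim signals. Its share in the values of C07G1.7, Y102A5C.35, Y102A5C.36 and fbxa-110 was not tested. When a probe had to be well above background on all 6 arrays, 1 gene changed, F56A4.3, by another of its probes (-4.33). Probes lost in a strain were then not tested, while haf-6 and lys-7 were, with the same differences of -2.29 and 2.37 but adjusted p of 0.101 and 0.1.

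Of the 8 named genes that fell, 6 lie on chromosome V, in 2 separate stretches in the gene order of assembly WBcel235. Y102A5C.35, Y102A5C.36, Y102A5C.6 and fbxa-110 are consecutive among the tested genes. Beside them Y102A5C.4 differed by -2.36 (adjusted p = 0.0784), and beyond Y102A5C.11 (-0.51) on the other side fbxa-111 differed by -2.18 (adjusted p = 0.0926). The other 2 genes, srbc-15 and F56A4.3, lie in a second stretch where 19 consecutive tested genes, from irld-32 to str-154, were all lower in the mutant. Of these, 2 passed the threshold and 15 had an unadjusted p under 0.05 by limma. The 17 that did not pass had a median difference of -1.93, with the lowest at -3.42. The first stretch lies in a run of 13 lower genes, from fbxa-206 to srh-206. Among runs of lower genes on chromosome V with a length other than 13 or 19, the longest was 11. Whether further runs of exactly 13 or 19 exist was not counted. The stretches and the genes in them other than those that changed were chosen after their values were seen.

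**Figure D2:**
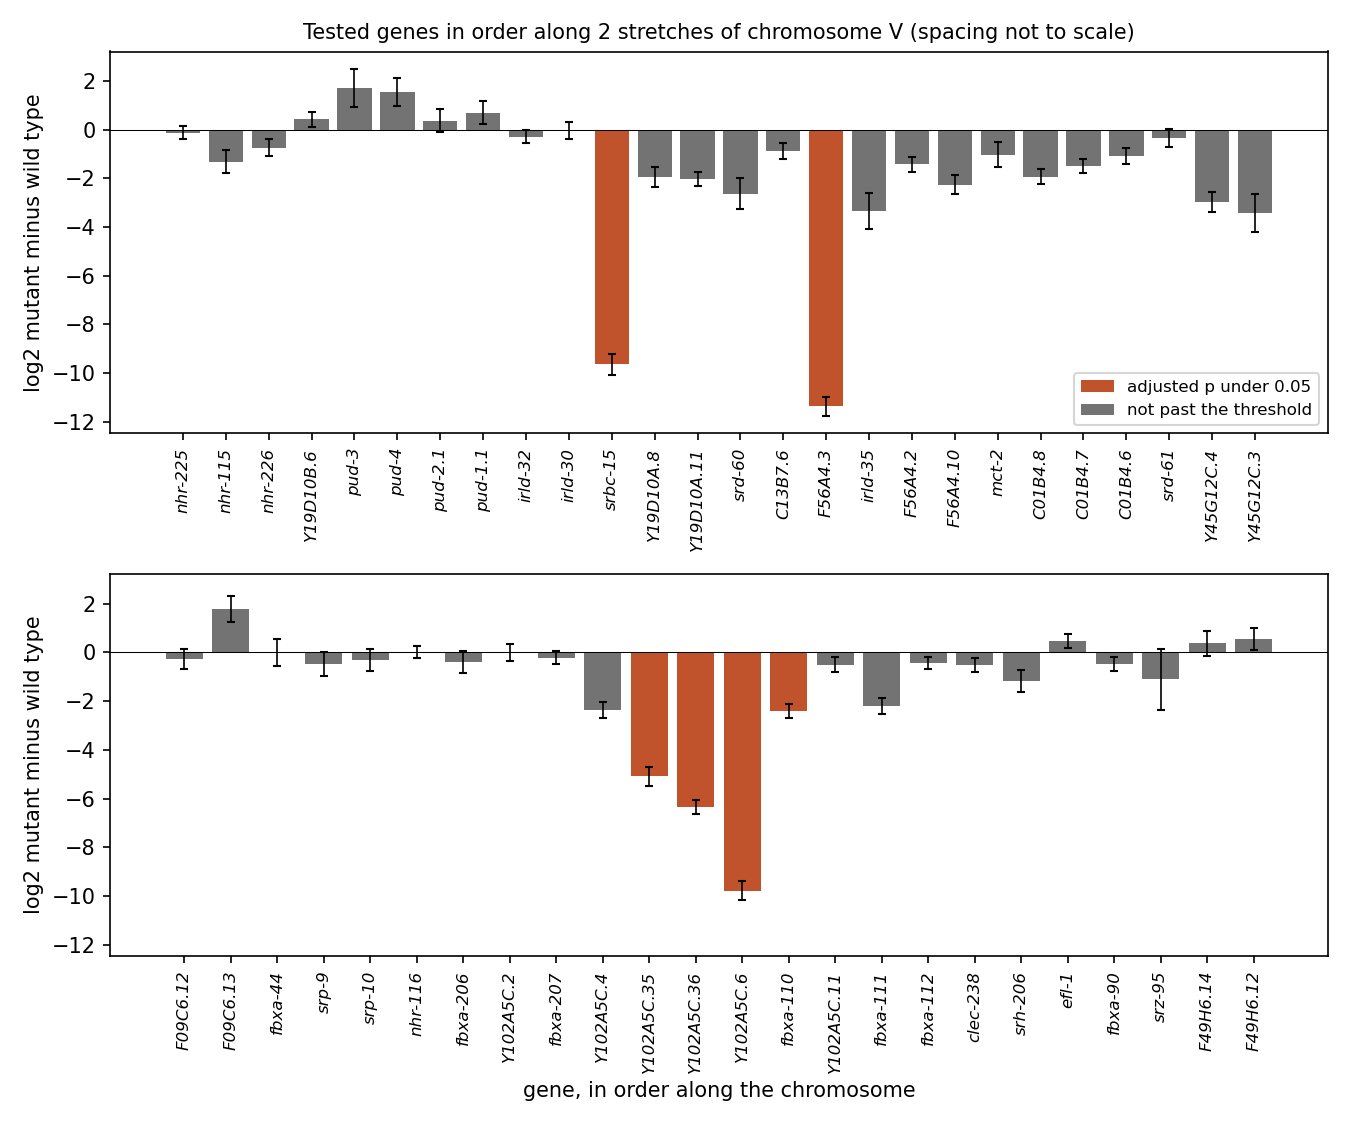
Difference of each tested gene (log2, mutant minus wild type, bars with SE) in gene order along 2 stretches of chromosome V, with 10 genes on each side of a gene that fell. Coloured bars mark genes past the adjusted threshold of 0.05; from srbc-15 to the end of the upper panel every gene is lower, and in the lower panel the fall reaches -9.79 at Y102A5C.6.

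Gene lists fixed before the data were examined were then tested as sets. Of 34 lists, 14 shifted by camera with a preset correlation of 0.01: 12 up and 2 down. None did with an estimated correlation (3 at an unadjusted p under 0.05) or by fry (5 at an unadjusted p under 0.05), whose lowest adjusted p values were 0.395 and 0.0808. In each other split of the 6 arrays into 3 and 3, between 3 and 17 lists were called with the preset correlation. Per list, single members rarely passed the test over all genes. The scores below are the mean deviation of a list's genes from their own 6-array means, compared between strains on each slide. For scores of 3 against 3 arrays the smallest two-sided p of an exact permutation test is 0.1.

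Sperm genes were lower in the mutant. Among 71 tested members 61 were lower and 10 higher, with a median difference of -0.44 (camera adjusted p = 1.52e-07; adjusted p = 0.395 with an estimated correlation). No member passed over all genes, nor did any adjusted over the list alone. The members with the smallest p were spe-27 (-1.23) and spe-38 (-0.99), both needed for sperm function, and nspd-3 (-0.95) and nspd-5 (-0.80). With normexp spe-38 gave -0.49. Sperm scores were 0.12 to 0.31 on the wild type arrays and -0.27 to -0.12 on the mutant arrays, and differed by -0.43 on slide 1 and by -0.39 on slide 2. Families sharing a symbol stem, examined after the data were seen, were less even. Medians on slides 1 and 2 were 0.03 and -0.71 for 34 spe genes, not all of them in the list. They were -0.61 and -0.14 for 27 msp genes and -0.52 and -0.27 for 11 ssp genes. On slide 2 both mutant arrays varied more between copies of a probe, so strain cannot be told apart from array quality there. Oocyte and eggshell genes were higher in 32 of 35 members, with a median of 0.47 (camera adjusted p = 6.31e-06; adjusted p = 0.517 with an estimated correlation). None passed over all genes or adjusted over the list alone, and oma-1 (0.87), egg-2 (0.71), pie-1 (0.88) and puf-6 (0.84) had the smallest p. The oocyte score differed by -0.17 on slide 1 and by 0.78 on slide 2, and the median was 0.18 without wild type 3. For pie-1 the difference was -0.02 on slide 1 and 1.33 on slide 2, and 0.54 without wild type 3 and without mutant 3. For egg-2 it was -0.17 on slide 1 and 1.14 on slide 2, while oma-1 and puf-6 were higher on both slides. Lists of germline proliferation and meiosis (median 0.15, adjusted p = 0.159), first zygotic genes (0.17, adjusted p = 0.279), vitellogenins (0.42, adjusted p = 0.38) and male genes (0.16, adjusted p = 0.78) did not shift by camera. Among vitellogenins, vit-2 differed by -0.35 (limma adjusted p = 0.782).

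Pharynx genes had the largest shift. Of 24 tested members 23 were higher, with a median of 1.17 (camera adjusted p = 1.65e-10; adjusted p = 0.395 with an estimated correlation). Over all genes 1 member rose, phat-5, and adjusted over the list alone 6 did. The next members were abu-6 (4.21), abu-8 (3.66) and abu-7 (3.23), whose products are prion-like proteins of the pharyngeal cuticle (limma adjusted p = 0.65 each). In the wild type abu-6 and abu-8 were well above background on 2 of 3 arrays and abu-7 on 1, so the sizes are uncertain: with normexp abu-6, abu-8 and abu-7 gave 2.96, 2.43 and 1.37, and abu-8 gave 2.40 without wild type 1. The arrays of a strain differed widely: the pharynx score was -1.79, 0.18 and -1.05 on wild type 1, 2 and 3 and 0.03, 1.69 and 0.95 on mutant 1, 2 and 3, with a difference of 1.82 on slide 1 and of 1.76 on slide 2 (exact permutation p = 0.2). These scores part without overlap not by strain but between wild type 1, wild type 3 and mutant 1 and the other arrays.

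Several other tissue and stage lists shifted up. Body wall muscle genes had a median of 0.35, with 24 of 28 higher (camera adjusted p = 0.000656; adjusted p = 0.517 with an estimated correlation), among them pat-2 (1.5), tni-3 (1.03) and the giant muscle proteins unc-22 (1.84) and unc-89 (1.64). Neuronal genes had a median of 0.30, with 33 of 40 higher (adjusted p = 0.000987; adjusted p = 0.395 with an estimated correlation), led by flp-21 (0.99), unc-25 (0.75), flp-5 (0.60) and cat-2 (0.57). Cuticle collagens had a median of 0.27, with 100 of 147 higher (adjusted p = 0.000987; adjusted p = 0.517 with an estimated correlation); col-77 (1.48), col-130 (1.87) and col-43 (0.89) were higher and col-75 (-2.09) lower. The adult collagen col-19 had no stable direction (-0.19 by its brightest probe, 0.15 by the mean of its probes and 0.02 on slide 2). Without mutant 2 col-130 gave 1.18, and with normexp col-75 gave -0.41. Moulting genes had a median of 0.33, with 18 of 26 higher (adjusted p = 0.012; adjusted p = 0.433 with an estimated correlation), led by mlt-7 (1.05), fbn-1 (1.42), noah-2 (1.02) and acn-1 (0.77). In the wild type fbn-1 was well above background on 1 of 3 arrays, and with normexp it gave 0.66. The difference of noah-2 was 0 on slide 1 and 1.52 on slide 2, while mlt-7, fbn-1 and acn-1 were higher on both slides. No member of these 4 lists passed over all genes, and none adjusted over the list alone. On slides 1 and 2 the scores differed by -0.02 and 0.87 for muscle, 0.41 and 0.22 for neurons, 0.09 and 0.48 for collagens and -0.03 and 0.50 for moulting. Both mutant arrays of slide 2 varied more between copies of a probe (22.4% and 20.9%) than its wild type arrays (8.74% and 10.9%). Within that slide strain cannot be told apart from array quality. The muscle scores overlapped between strains and parted by another split: -0.68 to -0.25 on wild type 1, wild type 3 and mutant 1, and 0.06 to 0.62 on the others. Without wild type 3 the medians were 0.23 for muscle, 0.17 for moulting and 0.09 for collagens, whose call ended (adjusted p = 0.374). Without mutant 1 they were 0.57 for muscle and 0.50 for moulting, and without mutant 2 0.19 for neurons and 0.17 for collagens. The neuron call ended on slide 2 alone (median 0.22, adjusted p = 0.051). The moulting call ended without wild type 2 (median 0.30, adjusted p = 0.0596) and without mutant 3 (0.16, adjusted p = 0.116). Hypodermis (median 0.25, adjusted p = 0.159), intestine (0.21, adjusted p = 0.253) and dauer and starvation genes (0.14, adjusted p = 0.279) did not shift by camera.

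Osmotic stress and glycerol genes were higher in 14 of 14 members, with a median of 0.46 (camera adjusted p = 0.000851; adjusted p = 0.395 with an estimated correlation). None passed over all genes, and 1 did adjusted over the list alone: gpdh-1, a glycerol-3-phosphate dehydrogenase of glycerol synthesis, which differed by 1.13 ± 0.26 (SE; limma adjusted p = 0.567 over all genes and 0.0324 over the list). The myo-inositol transporter genes hmit-1.1 and hmit-1.2 differed by 1.09 and 0.87, and the chloride channel gene clh-3 by 0.73. Glycogen and trehalose genes were higher in 17 of 18, with a median of 0.32 (adjusted p = 0.00458; adjusted p = 0.395 with an estimated correlation). Members included aagr-1 (0.90), tre-2 (0.60), gyg-2 (0.60), the glycogen phosphorylase pygl-1 (0.76) and the glycogen synthase gsy-1 (0.39). Genes of the AMP-activated protein kinase list were higher in 10 of 10, with a median of 0.43 (adjusted p = 0.00573; adjusted p = 0.517 with an estimated correlation), including aakg-3 (1.59), aak-2 (0.61), aakg-5 (0.53) and aakg-4 (0.44). No glycogen or kinase gene passed over all genes or adjusted over the list alone. Scores on slides 1 and 2 differed by 0.32 and 0.64 for osmotic stress, 0.11 and 0.49 for glycogen and 0.17 and 0.66 for the kinase. The osmotic median was 0.27 without wild type 3, and the kinase median 0.27 without wild type 1. The kinase scores, like those of pharynx genes, parted wild type 1, wild type 3 and mutant 1 from the other arrays and overlapped between strains. Differences of single genes also leaned on single arrays: pygl-1 gave 0.23 and gyg-2 0.30 without wild type 3, gsy-1 0.17 and clh-3 0.38 without mutant 3, and aakg-5 0.24 and hmit-1.1 0.57 without wild type 1. Further, hmit-1.2 gave 0.55 without mutant 3 and aakg-3 1.04 without wild type 2, and aakg-3 differed by -0.52 on slide 1 and 2.65 on slide 2. For aakg-4 the value was 0.29 without wild type 3 and -0.08 on slide 1, and for aak-2 it was 0.92 without wild type 2. The glycogen genes gyg-2, pygl-1 and gsy-1 differed by -0.22, -0.22 and -0.53 on slide 1 and by 1.01, 1.24 and 0.86 on slide 2. Both aagr-1 and tre-2 were higher on each slide.

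**Figure D3:**
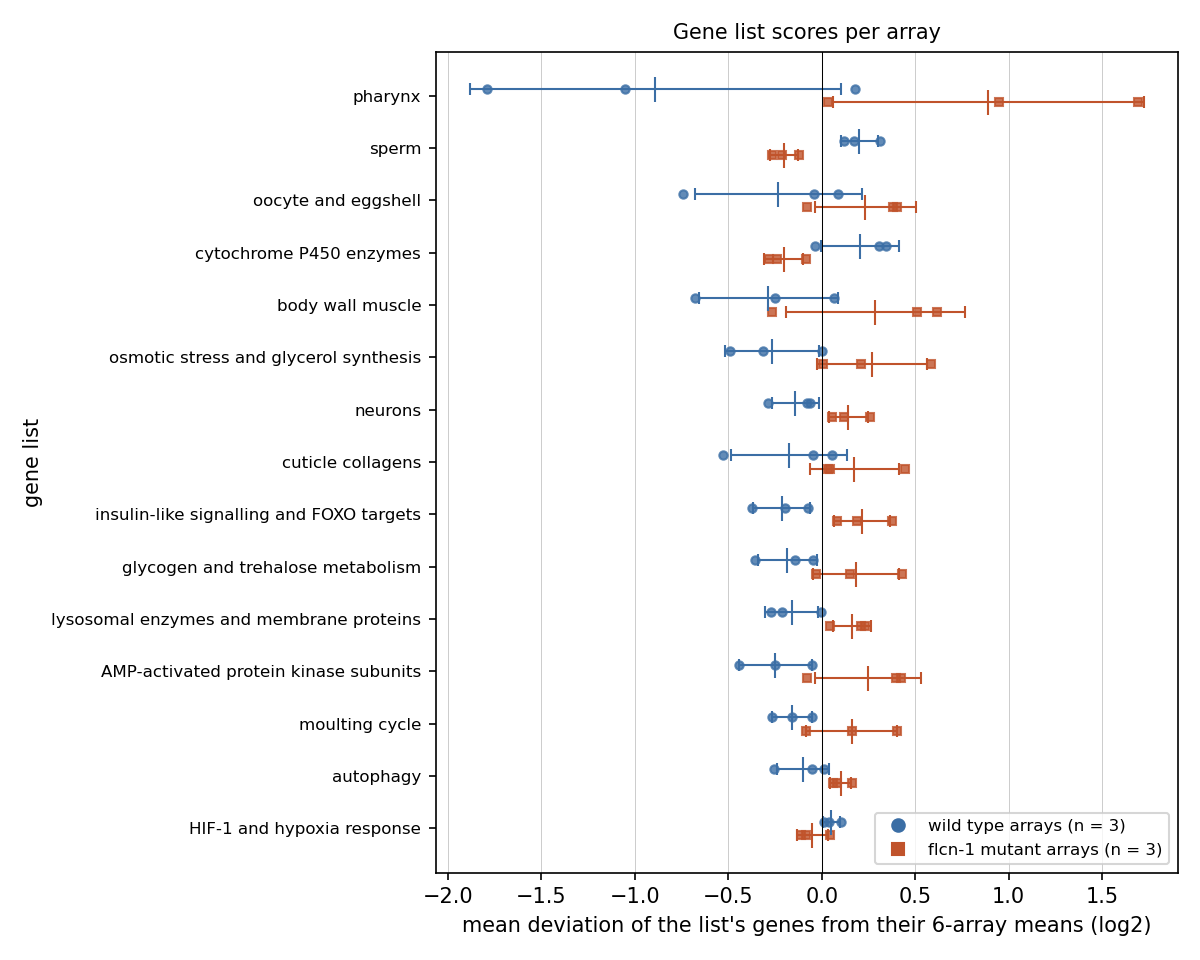
Score of each list that shifted, and of the HIF-1 list, on each array: the mean log2 deviation of its genes from their own 6-array means. Points are arrays, ticks are means and bars are SDs (n = 3 per strain). Sperm scores do not overlap between strains, while the pharynx score of wild type 2 (0.18) lies above that of mutant 1 (0.03).

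Insulin-like signalling and FOXO target genes were higher in 19 of 24, with a median of 0.41 (camera adjusted p = 0.00347; adjusted p = 0.395 with an estimated correlation). The list mixes genes of the pathway with target genes, so its shift is no measure of FOXO activity. Over all genes 1 member rose, lys-7, and the same count passed adjusted over the list alone. Beside it daf-28 (0.93), dod-6 (1.01) and icl-1 (1.01) had the smallest p, while sod-3, a superoxide dismutase, differed by -0.39 (limma adjusted p = 0.698). Lysosomal genes were higher in 32 of 46, with a median of 0.34 (adjusted p = 0.0048; adjusted p = 0.395 with an estimated correlation), led by the lipases lipl-3 (1.58) and lipl-1 (1.89), asp-14 (0.84) and cpz-1 (0.68). Autophagy genes were higher in 21 of 29, with a median of 0.19 (adjusted p = 0.0403; adjusted p = 0.395 with an estimated correlation), including sepa-1 (0.94), lgg-2 (0.61), epg-9 (0.58), epg-5 (0.57) and the transcription factor hlh-30 (0.53). No lysosomal or autophagy gene passed over all genes or adjusted over the list alone. Scores on slides 1 and 2 differed by 0.15 and 0.57 for the FOXO list, 0.04 and 0.46 for lysosomal genes and 0.07 and 0.27 for autophagy. The lysosomal median was 0.18 without wild type 3 and 0.19 without mutant 2. The difference of hlh-30 was 0.10 without wild type 3, that of lipl-1 1.03 without wild type 2 and 1.01 with normexp, that of sepa-1 0.56 without mutant 2 and that of sod-3 -0.1 without wild type 1. Without wild type 3 dod-6 gave 0.65 and epg-5 0.35, and without mutant 2 icl-1 gave 0.67. From the series value table epg-5 gave -0.04, and on slide 1 dod-6 differed by 0.07. The autophagy call held in 7 of 20 other settings. It ended with slide as a block (adjusted p = 0.052) and without wild type 2 (0.0639), wild type 3 (median 0.13, adjusted p = 0.173), mutant 1 (0.103) and mutant 2 (0.0839), and with normexp the FOXO and lysosomal calls ended too (adjusted p = 0.0552 and 0.0798).

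The HIF-1 and hypoxia list did not shift, with 8 members higher and 10 lower and a median of -0.25 (camera adjusted p = 0.678). Its regulator hif-1 differed by 0.59 (95% confidence interval -0.22 to 1.4), egl-9 by 0.38 (-0.37 to 1.13), rhy-1 by 0.10 (-0.66 to 0.87), the target cysl-2 by -0.21 (-0.97 to 0.56) and nhr-57 by -0.45 (-1.04 to 0.14). The list's median was -0.05 without wild type 1 and without wild type 2, and 0.08 with normexp. Without mutant 2 egl-9 differed by 0.17. Its sign was not stable: it differed by -0.17 on slide 1 and by 0.65 on slide 2, and 4 of its 6 probes were higher (-0.296 to 0.562). On slide 1 hif-1 differed by -0.36 and on slide 2 by 1.07. F22B5.4 differed by -0.84 and sqrd-1 by 0.56 (0.34 without mutant 2), with unadjusted p of 0.0597 and 0.122 by limma. The sign was not stable for rhy-1, which gave -0.03 with normexp and -0.02 from the series value table, nor for cysl-2, which gave 0.08 without wild type 1. Likewise not shifted by camera were TOR and Rag signalling (median 0.05, adjusted p = 0.713; fnip-2, the flcn-1 partner, differed by 0.47, and by 0.04 without wild type 3), the vacuolar proton ATPase (0.24, adjusted p = 0.156), glycolysis (0.30, adjusted p = 0.0898), oxidative phosphorylation (0.08, adjusted p = 0.368), fat metabolism (0.15, adjusted p = 0.159) and cytosolic ribosomal proteins (-0.04, adjusted p = 0.351).

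Cytochrome P450 genes were lower in 45 of 63 members, with a median of -0.25 (camera adjusted p = 0.000615; adjusted p = 0.395 with an estimated correlation). None passed over all genes, and 6 did adjusted over the list alone. The smallest p belonged to cyp-13A7 (-2.25, limma adjusted p = 0.0709 over all genes and 0.00518 over the list), cyp-13A5 (-1.29), cyp-13A6 (-2.01) and cyp-35C1 (-1.90). The cyp-13A genes named here lie on chromosome II, as does flcn-1, and cyp-35C1 lies on chromosome V. Whether the shared chromosome or similar sequences bear on these values was not tested. The size for cyp-13A6 is uncertain, since it was well above background on 2 of 3 mutant arrays and gave -0.45 with normexp. The score differed by -0.21 on slide 1 and -0.51 on slide 2, and the median was -0.16 without wild type 3, -0.38 without mutant 1 and 0.01 with normexp. Lysozymes and other intestinal immune effectors did not shift as a set (median 0.07, adjusted p = 0.283); lys-7 rose over all genes, and adjusted over the list alone 3 members did, with thn-1 (1.70) and thn-2 (1.49) beside it, while the next member, spp-12, was lower (-1.38; 0.0652 over the list). UDP-glucuronosyltransferases (-0.10, adjusted p = 0.173), C-type lectins (0.10, adjusted p = 0.173), heat shock proteins (0.09, adjusted p = 0.279) and oxidative stress and glutathione genes (-0.04, adjusted p = 0.822) did not shift by camera. Nor did the antimicrobial peptides (adjusted p = 0.804), whose median of 0.13 and mean of -0.02 differ in sign.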

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

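The fits with normexp on median signals and on slide 2 alone were chosen after the data were seen. The count of 20 features changed (also the count changed 2-fold or more) was 11 with normexp (which changed both the background method and the signal used), and 1 with the filter on all 6 arrays, which tests fewer features. It was 17 to 25 in the other settings without a block, 18 with the slide block, 17 to 20 without single arrays, and 18 on slide 2 alone. The 14 lists shifted became 0 with an estimated correlation and 0 with fry; other settings gave 13 to 16, and leaving out single arrays 13 to 17. With normexp the count was again 14, but 10 up and 4 down, with 11 of the lists shared. F56A4.3, Y102A5C.6, srbc-15 and phat-5 passed the threshold in every setting that tested them. Of other called genes, fbxa-110 passed in 5 of 18 settings, haf-6 in 6 of 19 and lys-7 in 8 of 19.

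The replicate numbers are shared between strains, but deviations from the strain means correlated by only 0.12, 0.12 and 0.02 across genes for numbers 1, 2 and 3, and not every sample correlated best with its own number, so the numbers were not taken as pairs. Arrays with number 1 share slide 1, and those with numbers 2 and 3 share slide 2. With the replicate block, 30 features changed (13 up and 17 down), 17 of them among the 20, and 13 lists shifted.

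Across the alternative settings signs turned for small differences and for the larger fall of fbxa-110 (-2.41). Within slide 1, with 1 array per strain, further differences turned, such as those of aakg-3 (1.59, and -0.52 there) and hif-1 (0.59, and -0.36 there). The causes were not tested. The flcn-1 difference became 0.04 with array weights, 0.25 on slide 2 alone, and ran from -0.23 to 0.07 without single arrays. With normexp fbxa-110 gave 0.08 and rhy-1 -0.03; from the series table rhy-1 gave -0.02 and epg-5 -0.04. Without single arrays rhy-1 ran from -0.1 (without wild type 3; -0.09 without mutant 3) to 0.35, cysl-2 from -0.44 to 0.08 (without wild type 1) and vit-2 from -0.68 to 0.13 (without wild type 1). Further turns were col-19 at 0.15 for the mean of its probes and 0.02 on slide 2, and vit-2 at 0.03 on slide 2. Genes not well above background in a strain have only a lower limit of their fold.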

Other observations

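The counts over splits of the arrays and the fits without single arrays were planned. The other tests in this part, and the use of those fits to weigh the patterns below, were chosen only after the result was seen. Families of genes sharing a symbol stem were scanned for groups that the fixed lists do not cover, with 145 families of at least 10 tested members. By camera with the preset correlation 23 shifted, and with an estimated correlation 0 did (adjusted p = 0.771 for each family named here). All 10 tested abu genes, some of which are also in the pharynx list, were higher, with a median of 3.37, and 8 passed adjusted over the family alone. Their median was 3.43 on slide 1 and 3.14 on slide 2, and 1.9 with normexp. The nspc family was higher in 17 of 17 members, with a median of 0.71 (0.26 on slide 1 and 0.87 on slide 2). The fbxa family of F-box genes was lower in 128 of 159, with a median of -0.29, but the median was 0.11 on slide 1, -0.47 on slide 2 and -0.01 with normexp.

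For the true grouping 20 features changed, each by 2-fold or more, while the highest count in any other of the 10 splits of the 6 arrays was 0. For gene lists, 2 of the 10 splits, the true one included, gave 14 or more, and the highest other was 17, for wild type 1 with mutants 2 and 3 against the rest. Every other split gave at least 3 lists, so a call with the preset correlation does not by itself mark a strain difference. As many features as in the true split were found in 1 split, itself. With 10 splits the share of splits cannot fall under 0.05. A split of wild type 1, wild type 3 and mutant 1 against the rest gave 3273 features at an unadjusted p under 0.05 by limma and 0 after adjustment, against 1431 for the strains, which points to a structure of the samples beyond strain. The scores of the pharynx, body wall muscle and AMP-activated protein kinase lists follow that split without overlap and overlap between strains.

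The first pattern is the loss of chromosome V transcripts. For F56A4.3, Y102A5C.35 and srbc-15 a spot defect is argued against by their 8 other probes, all lower, with a median of -4.47. The other 3 lost genes (Y102A5C.6, Y102A5C.36 and fbxa-110) have 1 kept probe, so other probes cannot check them. For Y102A5C.6 and Y102A5C.36 the arrays argue against a spot defect. Their levels were 1.59 to 2.25 and -2.57 to -2.21 on the wild type arrays. On the mutant arrays of both slides they were -8.67 to -7.34 and -9.03 to -8.4. For the dim fbxa-110 a spot defect stays open. DNA kept with flcn-1 through the backcrosses is argued against as the source of most calls of named genes, since 0 of these 10 lie on its chromosome, II. The unnamed probes that changed have no chromosome and are not covered. This explanation stays open for cyp-13A5, cyp-13A6 and cyp-13A7, which lie on chromosome II and were lower without passing the threshold. A DNA difference between the strains at these stretches, such as missing copies, is a hypothesis made from the lower neighbours themselves, so their count (16 of 44 that did not pass were lower at an unadjusted p under 0.05) describes the pattern and does not test it. It cannot be told apart from joint regulation of neighbours by flcn-1, as only 1 strain carries the allele and no DNA was measured.

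The second pattern is that sperm genes were lower and oocyte genes higher. The missing detrending of mutant array 2 is argued against for sperm genes, whose median was -0.35 without that array and still past the threshold with the preset correlation. Mutant animals further into adulthood might show the same shift, and this cannot be told apart from an effect of the allele: the moulting score, which should then be lower, was 0.32 higher with overlapping arrays, and the vitellogenin score overlapped too. Neither list holds with an estimated correlation, which was 0.504 for oocyte genes and 0.031 for sperm genes. Genes that vary together between samples remain a further open explanation for oocyte genes. For sperm genes this stays open too, but the lost call alone does not show it. The FOXO list also lost its call, at an estimated correlation of 0.007, below the preset 0.01.

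The third pattern is the higher level of pharynx genes. A single array is argued against, as the lowest median with 1 array left out was 0.80, still past the threshold with the preset correlation. The score differences were 1.76 or more on both slides. Each slide held both strains in equal numbers, so a shift shared by a slide's arrays would cancel, and these values do not test it. Slide 1 holds 1 array per strain, and on slide 2 strain cannot be told apart from array quality. A difference between batches of animals stays open, because the scores follow the split given above and the estimated correlation between these genes was 0.56, and so does the allele itself.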
